A study of Mus musculus with 12 samples.

How the data were processed

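The values analysed are the counts the authors deposited. The mRNA matrices hold raw UMI counts per gene and cell barcode, with counts for the 4 antibodies below them, and per the file headers Cell Ranger 4.0.0 wrote them. The submitters' processing notes name the mouse genome build mm10 and Seurat, with no version for Seurat and no role for either. Every barcode deposited had at least 500 UMIs, so barcodes were selected before deposit. The contig tables of the TCR libraries give counts of UMIs and of reads per assembled contig, per the file headers in the format of 10x V(D)J filtered contigs, and the software version is not given in the sources used here. The labels list antibody libraries apart, and their counts were read from the mRNA matrices.

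Barcodes were kept with at least 500 UMIs, at least 300 genes, at most 8% mitochondrial UMIs, at least 1 UMI of Cd3d, Cd3e or Cd3g and at most 1 TRB chain. Predicted doublets and cells in clusters named after other cell types were left out. This also removed barcodes with a T cell receptor chain. A TRB chain was read in 76.9% of the 553 barcodes of the acinar-like cluster, 299 of them from replicate 2, and in 72.0% of the 742 of a B cell-like cluster. Barcodes of this B cell-like cluster held a median of 2.096 times the median UMI count of their library. T cells and doublets of a T and a B cell were not told apart there. Scrublet, which scores barcodes against simulated doublets, called only 9 of 27423 barcodes and so hardly worked here, while 1370 barcodes held 2 TRB chains. Leaving out the top 5% of its scores was therefore added as an alternative after seeing the data. Cells were clustered in scanpy on 2000 variable genes, without TCR and immunoglobulin segments, 30 principal components and 15 neighbours, by the Leiden method at resolution 1. A cluster was named after a fixed marker list when at least 3 markers and 40% of the list were at least 2-fold above the other clusters and at least 1 marker was among its 10 leading genes. A T cell state also needed a median CD11a count of at least 20 and no other cluster marker list with more of those 10 genes, and these marker lists hold no dissociation genes. These naming thresholds were chosen after seeing the data.

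Gates were set in each library by Gaussian mixtures of 2 components on log10 antibody counts. The CD4 threshold lay between 20.7 and 44.4 counts and the CD62L threshold between 3.65 and 12.9. The CD11a threshold within CD4 cells lay between 143 and 202. The PE threshold lay between 0.083 and 0.087, so any PE count made a cell CD8b-high. Treg were cells in the CD4 gate with a Foxp3 UMI or in a Treg-like cluster, and the other CD4 cells were called CD4 conventional. Because droplets carry free RNA, a Foxp3 UMI can also mark a conventional cell. A population was used with at least 20 cells in a library, and the sums tested held 46 to 2795 cells. Cycling cells, those with at least 2 UMIs over the cycling genes, carry many UMIs per cell and so weigh on the sums more than on the cell counts.

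A clonotype was the set of productive TRA and TRB CDR3 nucleotide sequences of a cell with exactly 1 TRB and 1 or 2 TRA chains. Clonotypes were matched within a library, and clones of at least 2 cells were called expanded. Of the TCR barcodes, 4990 of 5024, 3402 of 3426, 4955 of 4965 and 5175 of 5280 were found in the mRNA library of their own replicate and at most 68 in that of another. A TRB chain was read in 84.7%, 86.1%, 62.3% and 62.2% of the kept barcodes of replicates 1 to 4. A paired receptor was read in 73.4%, 77.3%, 71.1% and 70.3% of CD4 conventional cells, 73.2%, 70.7%, 62.9% and 59.5% of CD8 cells and 71.1%, 75.0%, 65.8% and 69.8% of Treg, and cells without one are in no clone. In the comparisons of expanded shares, clones were counted within the cells of a group alone. These shares were means over 100 thinnings to equal cell numbers within a library.

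UMI sums per population and library were tested in edgeR 4.0.16 with filterByExpr, TMM scaling, a robust quasi-likelihood fit and the replicate as block, since the populations compared come from the same library. The residuals of the paired populations correlated within replicates by 0.122 to 0.679, except in the CD62L comparison of CD8 cells, where replicates 2 (−0.034) and 4 (0.085) gave no sign of pairing. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 were called. V genes were tested in the same way on clonotype counts, TRAV and TRBV apart. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry in limma 3.58.1. The lists covered stemness and memory, exhaustion, cytotoxic, Th1, Tfh, Th17, Treg, anergy, proliferation, TCR signalling, interferon response, tissue residence, recirculation, chemokine receptor and dissociation genes, and markers of B cells, myeloid cells, NK cells, γδ T cells, iNKT and MAIT cells, endocrine cells, acinar and ductal cells, and stroma and endothelium. Cell filters, comparisons, lists, tests and the rule for named genes were chosen before the data were examined.

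The named genes of a comparison were the 8 with the largest fold in each direction among genes with an adjusted p under 0.05, a mean log2 CPM of at least 5 and the same direction in all 4 libraries, leaving out predicted, ribosomal, mitochondrial, TCR and immunoglobulin segment genes. The up to 4 members of each list with the smallest p were added. So were Cd4, Cd8a, Cd8b1, Foxp3 and Itgal, and in every comparison Tcf7, Slamf6, Pdcd1, Lag3, Havcr2, Tox, Tigit, Il7r, Ifng, Gzmb and Mki67. Some genes named by this rule are not reported here and are left out of the counts of named gene values under the alternatives.

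In a self-test, changes were added to 200 genes of simulated counts with the depth and spread of the data. Of changes of 1 log2 unit 70.1% to 100% were recovered, and of changes of 0.5 units 13.4% to 74.6%. False calls made up 9.6%, 5.1%, 8.6%, 12.1%, 3.1%, 5.5%, 7.3%, 8% and 4.7% of all calls, at a nominal 5%, in the order CD8 against CD4 conventional cells, the same in CD62L-low cells, CD62L in CD4 conventional cells, CD62L in CD8 cells, the CD62L interaction, CD11a, clone size in CD4 conventional cells, clone size in CD8 cells and the clone size interaction. Other fitting settings tried on the simulated counts gave no clear gain, and the planned ones were kept. For V genes the self-test recovered 4 of 6 changed TRAV genes with 1 false call and 6 of 6 TRBV genes with none.

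Alternatives were DESeq2 size factors and the DESeq2 1.42.0 Wald test, no low-count filter, no replicate block, each replicate left out, equal cell numbers, doublets kept, stricter cell filters (at most 5% mitochondrial UMIs and at least 1000 UMIs), another antibody gate, lineage by Cd4 and Cd8 UMIs, 1 cell per clonotype, cycling cells left out, only cells with a TRB chain, clones by TRB alone, expanded clones of at least 3 cells, no thinning, and V usage by cells. Added after seeing the data were a CD11a count of at least 20, the top doublet scores left out, replicates 1 and 2 only, CD62L-low cells only, the Tfh-like cluster left out, and cycling cells left out in the comparisons where this was not planned. Other tools were Python 3.11.15 with scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3. Intervals and limits cover counting error only. CD11a gates in CD8 cells and the read counts of contigs were not used here.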

Results

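T cells from the pancreatic islets of pre-diabetic female NOD mice, a strain in which autoimmune diabetes arises spontaneously, were profiled at 12 weeks of age by CITE-seq, which counts mRNA molecules and antibody tags in the same cell. Live cells stained for the αβ T cell receptor had been sorted, and 4 biological replicates each gave an mRNA library with antibody counts and a T cell receptor (TCR) library. The antibodies read CD62L, the lymph node homing receptor, CD11a, an integrin chain encoded by Itgal that activated T cells carry at high levels, CD4, and CD8b through a PE tag. Replicates 1 to 4 held 6175, 4136, 8718 and 8394 cell barcodes with 34661827, 26861163, 37834174 and 32141055 RNA UMIs (unique molecular identifiers, each standing for a captured molecule). After filtering, 4902, 3026, 6347 and 7038 barcodes with mRNA of CD3 chains were kept, with a median of 3833, 4316, 3190 and 2578.5 UMIs each. Both a TRA (α) and a TRB (β) chain were read in 3496, 2232, 3308 and 3605 of them. The share of barcodes with a CD11a count under 20 was 5.3% and 6.6% in replicates 1 and 2 but 37.3% and 31.2% in replicates 3 and 4. The labels do not say whether a replicate is a single mouse or a pool. The p-values of single genes, V genes and exact permutation tests therefore measure the spread between these samples.

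CD4 conventional cells, those in the CD4 gate without Foxp3 mRNA and outside the Treg-like clusters, made up 44.94% ± 6.48 (SD, n = 4) of the kept barcodes. CD8 cells made up 16.9% ± 2.79 and regulatory T cells (Treg) 8.38% ± 2.65. A further 8.75% ± 3.36 passed both gates. Before the doublet filter 15.896% of such cells with a TRB chain held 2 TRB chains, against 4.865% in the CD8 gate and 6.376% in the CD4 gate. Another 21.03% ± 13.79 passed neither gate, a share that was 33.134% and 32.793% in replicates 3 and 4 but 7.42% among cells with a CD11a count of at least 20. Many of these barcodes lay in the unnamed clusters 3, 7 and 15, of 1731, 992 and 562 kept barcodes nearly all from replicates 3 and 4, where only 9.0%, 6.8% and 3.9% held a TRB chain. That these are T cells was not shown, and the shares of CD4 conventional cells, CD8 cells and Treg have them in the denominator. Clusters 3, 7 and 15 also entered the populations compared. They gave 139, 81 and 39 of the CD8 cells, 91, 69 and 33 of the CD4 conventional cells and 4, 2 and 4 of the Treg. All barcodes of these clusters held a median of 0.355, 0.284 and 0.256 times the median UMI count of their library. CD62L-high cells were 37.81% ± 8.1 of CD4 conventional cells, 31.64% ± 9.95 of CD8 cells and 26.62% ± 3.96 of Treg. CD11a-high cells were 8.65% ± 3.04 of the CD62L-high and 53.67% ± 7.9 of the CD62L-low CD4 conventional cells. With lineage by UMIs these shares were 52.32% ± 52.21 and 64.32% ± 20.15, and the first ran from 4.09% to 98.25% over the libraries.

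Clustering by mRNA placed the CD4 conventional cells mainly in naive or recirculating-like clusters (31.76% ± 9.26 and 10.5% ± 4.84), a Tfh-like cluster (17.93% ± 3.55) named for follicular helper genes, a cycling-like cluster (3.35% ± 0.55) and a Th1-like cluster (2.42% ± 1.75). Of the 10 leading genes of the second naive-like cluster, 4 were dissociation genes (Fos, Jun, Hspa1a and Hspa1b) and 2 naive markers (Klf2 and Lef1). A further 17.84% ± 7.51 lay in a cluster that met no naming rule. CD8 cells fell mainly into a naive or recirculating-like cluster (30.72% ± 9.73), cytotoxic clusters (14.04% ± 4.2, 14.17% ± 6.02 and 5.65% ± 3.39) and a cycling-like cluster (10.72% ± 5.49). In the 5.65% cluster every marker of the exhausted-like list was also at least 2-fold up, Pdcd1, Havcr2 and Cd101 among them. In the 14.17% cluster Pdcd1, Lag3, Tox and Nr4a2 were, but neither Prf1 nor a listed granzyme gene. In the Th1-like cluster Pdcd1, Lag3, Havcr2, Tigit, Tox and Entpd1 were. In the Tfh-like cluster 3.56% ± 1.27 of the CD4 conventional cells were CD62L-high, against 69.52% ± 6.51 in the larger naive-like cluster. Clones of at least 2 cells held 74.34% ± 9.64 of the CD4 conventional cells with a paired receptor in the Tfh-like cluster, 87.87% ± 3.94 (n = 3) in the Th1-like cluster and 4.42% ± 3.12 in the larger naive-like cluster. Among CD8 cells the corresponding shares were 92.13% ± 6.73 in the cycling-like cluster, 83.19% ± 8.69 and 40.3% ± 4.16 in the larger cytotoxic clusters, and 2.58% ± 2.03 in the naive-like cluster. Cluster names come from marker genes, so they describe the clusters and do not test those genes.

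**Figure D1:**
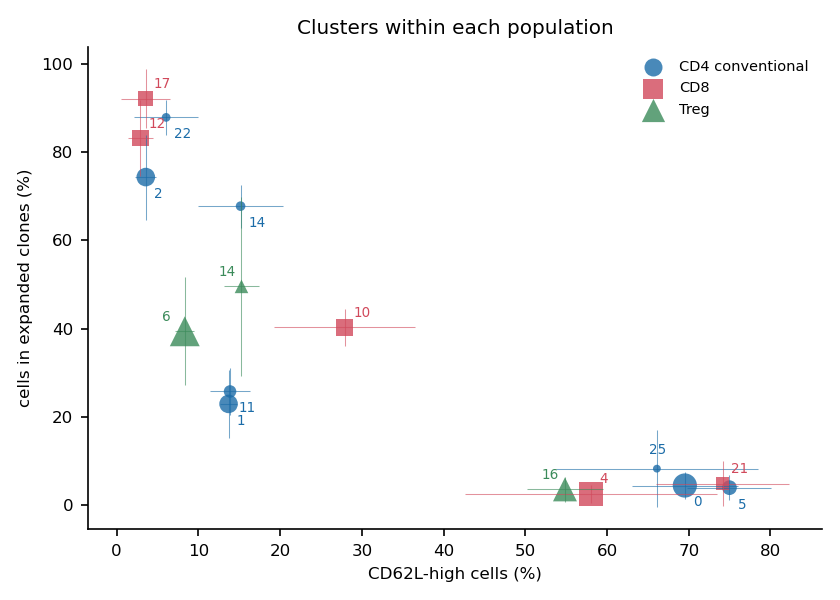
Share of cells that were CD62L-high (x axis, %) against the share of cells with a paired receptor that were in expanded clones (y axis, %) for each cluster, numbered, within CD4 conventional cells (circles), CD8 cells (squares) and Treg (triangles), with size rising with the cluster's share of its population, error bars showing the SD between libraries, and only clusters with values in at least 3 libraries drawn. The CD62L-high clusters lie low, as for the larger naive-like CD4 conventional cluster (69.52% CD62L-high, 4.42% expanded), and the cycling-like CD8 cluster lies highest (3.55% and 92.13%).

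The share of cells in expanded clones (2 or more cells with the same paired receptor) was compared after thinning to equal cell numbers, to ask where clonal expansion sits. Within a library CD8 cells, CD4 conventional cells and Treg were thinned together to the smallest of the 3, 263 to 356 cells, and the CD62L states of each population to the smaller, and the shares depend on these depths. CD8 cells had 36.61% ± 13.96 (SD, n = 4) of their cells in expanded clones and CD4 conventional cells 16.83% ± 4.29, a difference of 19.77 ± 12.62 percentage points that was positive in 4 of 4 libraries. Without thinning it was 12.45 ± 10.95, with 0.1 in replicate 1. Clones were counted within each compared group alone, so a CD62L-high cell whose clone mates were all CD62L-low counted as single. By this count few CD62L-high cells of each population were in expanded clones. The share was 2.83% ± 2.4 in CD62L-high and 36.13% ± 1.91 in CD62L-low CD4 conventional cells, 4.32% ± 2.81 and 50.43% ± 15.94 in CD8 cells, and 3.04% ± 2.25 and 17.63% ± 9.8 in Treg, lower on the CD62L-high side in every library. The Treg difference of −14.59 ± 10.13 was −1.51 in replicate 3, −25.76 without thinning and −9.33 for clones of at least 3 cells. Treg and CD4 conventional cells differed by 6.88 ± 10.03 points, positive in 2 of 4 libraries, which is within the spread between replicates (exact permutation test, two-sided p = 0.5), and without thinning by −3.9 ± 11.1. Each of the other differences had an exact two-sided permutation p of 0.13, the smallest that 4 pairs allow, so none could pass 0.05. Without replicate 1 the difference between Treg and CD4 conventional cells was 3.52. In the CD8 cells of replicate 3 a single clone held 109 cells, 17.69% of those with a paired receptor.

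**Figure D2:**
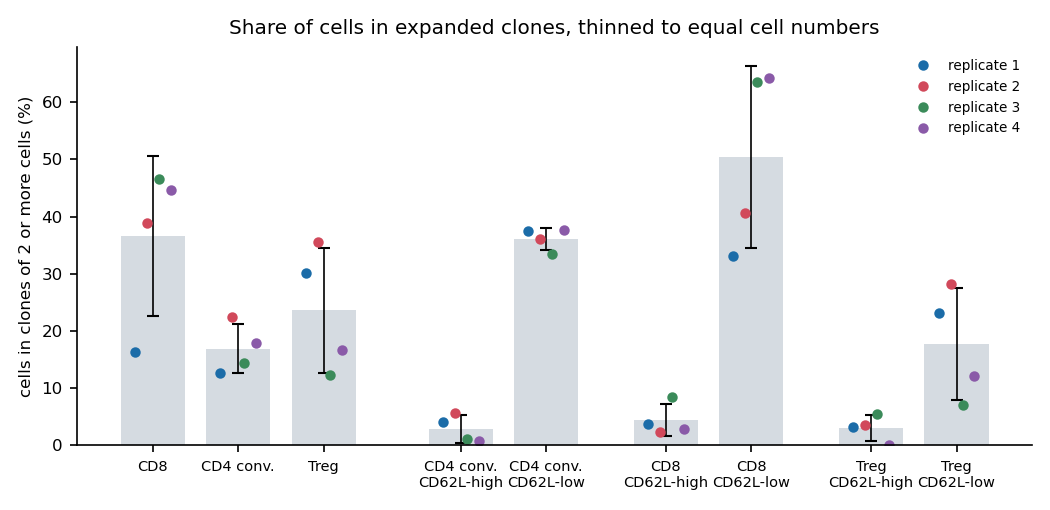
Percentage of cells with a paired receptor in clones of at least 2 cells, counted within the group alone after thinning to equal cell numbers within each compared group, with bars for the mean of 4 libraries, error bars for the SD and points for single libraries. CD62L-low bars stand far above CD62L-high bars, as in CD8 cells (50.43% against 4.32%).

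Genes were tested on UMI sums per population and library (n = 4 sums a side, 471759 to 11903675 UMIs each) by edgeR's quasi-likelihood test with the replicate as block, and p-values were adjusted by Benjamini-Hochberg over all tested genes. Values are log2 fold changes ± SE, and each gene given as higher or lower went that way in 4 of 4 libraries unless stated. Gene lists fixed before the data were examined were tested with camera at a preset correlation, and the adjusted p with an estimated correlation stands beside each call.

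CD62L-high and CD62L-low CD4 conventional cells were compared to ask what goes with CD62L, since the study's title names a stem-like, recirculating state. The main naive or recirculating-like clusters were 69.52% and 74.98% CD62L-high, with 4.42% and 3.93% of their paired cells in expanded clones. The CD62L-high side thus holds many naive-like cells, and this contrast cannot tell a stem-like state from a naive one. In CD62L-high cells the naive T cell genes Dapl1 (2.27 ± 0.16) and Satb1 (1.98 ± 0.07, adjusted p = 1.7e-10) were higher. Pdcd1, which encodes the inhibitory receptor PD-1, was lower by 2.44 ± 0.08 (adjusted p = 1.4e-16), Lag3 by 2.63 ± 0.27, Tigit by 2.77 ± 0.29 and Havcr2, which encodes TIM-3, by 3.31 ± 0.33. Tox, a transcription factor of exhausted T cells, was lower by 1.16 ± 0.05 and the related Tox2 by 2.97 ± 0.19. Tcf7, which encodes the stem-like T cell factor TCF-1, was higher by only 0.20 ± 0.04, and Slamf6, a marker of stem-like exhausted cells, was lower by 0.79 ± 0.05 (adjusted p = 2.0e-11). Of the 10583 tested genes 4932 passed, 2465 higher and 2467 lower in CD62L-high cells, with 2946 by the DESeq2 Wald test and 3017 with 1 cell per clonotype. The stemness and memory list had 15 of 18 tested members higher, among them S1pr1 (1.01 ± 0.05), Bach2 (1.56 ± 0.07) and Foxp1 (1.13 ± 0.05), and only Slamf6 lower (adjusted p = 2.8e-26, adjusted p = 0.0669 with an estimated correlation). The exhaustion list had 18 of 22 lower and none higher (adjusted p = 1.8e-26, adjusted p = 0.0669 with an estimated correlation). The Tfh list had 14 of 14 lower, including Cxcr5, the receptor for B cell follicles, at −2.38 ± 0.18 and Ascl2 at −3.15 ± 0.33 (adjusted p = 8.8e-22, adjusted p = 0.0811 with an estimated correlation). The Th1 list had 14 of 15 lower and 1 higher, with Tbx21, which encodes T-bet, at −2.12 ± 0.13 (adjusted p = 3.3e-12, adjusted p = 0.0851 with an estimated correlation).

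Tissue residence genes were lower in 9 of 12 and higher in 2, with Cxcr6 at −2.99 ± 0.12, Itga1 at −3.41 ± 0.44 and the chemokine gene Xcl1 at −4.21 ± 0.26 (adjusted p = 9.0e-10, adjusted p = 0.0669 with an estimated correlation). Chemokine receptor genes were lower in 8 of 11 and higher in 1, with Ccr2 at −2.47 ± 0.16 (adjusted p = 2.1e-08, adjusted p = 0.0669 with an estimated correlation). Recirculation genes were higher in 7 of 11, such as Rasgrp2 at 1.13 ± 0.06, and Itga4 was lower by 0.69 ± 0.07 (adjusted p = 2.1e-07, adjusted p = 0.124 with an estimated correlation). Cytotoxic genes were lower in 11 of 17 and higher in 2 (13 and 2 when adjusted over the list alone), with Klrk1 at −1.76 ± 0.34 but Prf1, the perforin gene, at 1.81 ± 0.12 (adjusted p = 1.0e-07, adjusted p = 0.0669 with an estimated correlation). Treg genes were lower in 9 of 15 and higher in 1 (11 and 1 when adjusted over the list alone), with Ikzf2 at −2.09 ± 0.08 (adjusted p = 3.4e-10, adjusted p = 0.114 with an estimated correlation). Anergy genes were lower in 9 of 14, with Nt5e, which encodes CD73, at −2.52 ± 0.12, and higher in 4, with Dgka at 0.78 ± 0.04 (adjusted p = 5.9e-07, adjusted p = 0.114 with an estimated correlation). TCR signalling genes were lower in 7 of 15 and higher in 2, with Egr2 at −1.35 ± 0.12 (adjusted p = 0.00035, adjusted p = 0.291 with an estimated correlation). Proliferation genes were lower in 18 of 22 (22 when adjusted over the list alone), with Mcm6 at −1.49 ± 0.10 (adjusted p = 1.1e-13, adjusted p = 0.272 with an estimated correlation). Mki67 at −1.16 ± 0.33 did not pass. Interferon response genes were higher in 11 of 18 and lower in 3, with Ifi47 at 0.71 ± 0.05 (adjusted p = 0.005, adjusted p = 0.616 with an estimated correlation). The Th17 list had 2 of 4 lower and was not called (adjusted p = 0.0692). Among markers of other cells, 3 of 6 acinar genes were lower (4 when adjusted over the list alone) and 2 of 5 myeloid genes were lower (1 over the list alone). Of B cell genes 2 of 4 and of endocrine genes 1 of 4 were higher, 1 of 3 γδ T cell genes was lower and none of 3 NK cell genes changed. None of these lists was called. The NK list had a median of 0.037 and a mean of 0.052 against a downward test direction. Dissociation genes were higher in 4 of 14 and lower in 2 (median 0.152, mean −0.04), without a call (adjusted p = 0.452).

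CD8 cells were compared in the same way. CD62L-high CD8 cells had more Ccr7, the chemokine receptor for lymph node entry (1.71 ± 0.21), Klf2, the factor that drives S1pr1 (1.40 ± 0.11), and S1pr1, the receptor for lymph node exit (1.54 ± 0.16). They had less Pdcd1 (−2.64 ± 0.19, adjusted p = 6.2e-05), Lag3 (−2.37 ± 0.14, adjusted p = 1.0e-05), Tigit (−2.56 ± 0.35), Havcr2 (−3.10 ± 0.35) and Tox (−1.24 ± 0.12). The chemokine genes Xcl1 (−3.12 ± 0.12, adjusted p = 4.0e-07) and Ccl3 (−3.70 ± 0.36) and the survival gene Bcl2a1d (−2.75 ± 0.15) were also lower. Of 9786 tested genes 3057 passed, 1470 higher and 1587 lower, and without replicate 3 the count was 1868. Without cycling cells it was 1660, with 1 cell per clonotype 558 and by the DESeq2 Wald test 1978. The stemness list had 16 of 18 higher (17 when adjusted over the list alone) and none lower (adjusted p = 5.4e-21, adjusted p = 0.186 with an estimated correlation). Slamf6 was on that side at 0.41 ± 0.13 in 3 of 4 libraries and Tcf7 at 0.59 ± 0.18, but Slamf6 did not pass without replicate 2 (0.46), 3 (0.31) or 4 (0.29), nor Tcf7 without replicate 3 (0.46) or 4 (0.43). Without cycling cells Slamf6 was −0.22 and Tcf7 0.15, and neither passed. The exhaustion list had 19 of 22 lower (21 when adjusted over the list alone) and none higher, with Cd38 at −2.20 ± 0.17 (adjusted p = 2.4e-24, adjusted p = 0.152 with an estimated correlation). Cytotoxic genes were lower in 13 of 19 and higher in 1, with Klrk1 at −1.48 ± 0.12 and Nkg7 at −0.78 ± 0.07 (adjusted p = 4.8e-14, adjusted p = 0.152 with an estimated correlation). Proliferation genes were lower in 20 of 22 (22 over the list alone), with Tk1 at −1.70 ± 0.14 (adjusted p = 8.2e-20, adjusted p = 0.2 with an estimated correlation). Tissue residence genes were lower in 8 of 12 and higher in 1, with Rgs1 at −2.03 ± 0.13 (adjusted p = 1.9e-09, adjusted p = 0.152 with an estimated correlation).

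Treg-associated genes in the CD8 cells were lower in 7 of 11 and higher in 1 (9 and 1 when adjusted over the list alone), with Tnfrsf9, which encodes 4-1BB, at −2.35 ± 0.24 (adjusted p = 7.2e-07, adjusted p = 0.2 with an estimated correlation). Recirculation genes were higher in 9 of 11 and lower in 1 (9 and 2 over the list alone, adjusted p = 4.1e-07, adjusted p = 0.2 with an estimated correlation). Interferon response genes were higher in 11 of 16 and lower in 1 (11 and 2 over the list alone), with Gbp2 at 1.5 ± 0.19 (adjusted p = 5.3e-06, adjusted p = 0.318 with an estimated correlation). Tfh genes were lower in 8 of 9 and higher in 1, with Cd200 at −1.92 ± 0.21 (adjusted p = 7.3e-05, adjusted p = 0.2 with an estimated correlation). Th1 genes were lower in 7 of 14 and higher in 1 (9 and 1 over the list alone), with Ifng at −1.78 ± 0.16 (adjusted p = 0.00099, adjusted p = 0.273 with an estimated correlation). Chemokine receptor genes were lower in 7 of 9 and higher in 1 (8 and 1 over the list alone), with Ccr8 at −3.36 ± 0.47 (adjusted p = 0.00091, adjusted p = 0.219 with an estimated correlation). The γδ T cell list was lower in 2 of 3, with Tcrg-C4 at −3.44 ± 0.23 (adjusted p = 7.3e-05, adjusted p = 0.152 with an estimated correlation). The anergy list (6 of 13 lower and 2 higher), the TCR signalling list (4 of 15 lower and 5 higher) and the dissociation list (6 of 13 higher and 2 lower) were not called. Nor were the myeloid (2 of 3 lower), B cell (2 of 4 higher and 1 lower) and acinar lists (1 of 5 lower).

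The CD62L effect was then tested for a difference between lineages, with positive values meaning a higher CD62L-high to CD62L-low ratio in CD8 than in CD4 conventional cells. Art2b, a surface ADP-ribosyltransferase of T cells (2.30 ± 0.30, adjusted p = 0.0014), Arhgap26 (1.56 ± 0.22) and Gprin3 (1.57 ± 0.26) were relatively higher with CD62L in CD8 cells. So were Stat4, a signal transducer of Th1 cells (1.03 ± 0.14), and Nfatc1, a TCR-driven transcription factor (0.94 ± 0.12, adjusted p = 0.00024). Prf1 (−1.78 ± 0.17, adjusted p = 6.9e-06), Cers6 (−2.04 ± 0.22), Cd7 (−1.64 ± 0.20), Itm2a (−1.41 ± 0.19) and Gpr18 (−1.30 ± 0.15) were relatively lower. The Slamf6 interaction was 1.19 ± 0.22 (adjusted p = 0.0148, range over the alternatives 2.9e-06 to 0.129), and it did not pass without replicate 2 (1.30), 3 (1.06) or 4 (1.08) or without the Tfh-like cluster (0.82). Pdcd1 (−0.16 ± 0.26), Lag3 (0.29 ± 0.33), Tigit (0.28 ± 0.51), Havcr2 (0.28 ± 0.64) and Tox (−0.04 ± 0.14) gave no call, so no lineage difference in their CD62L effect was detected. Of 10675 tested genes 256 passed, 186 positive and 70 negative, with 94 without replicate 3, 60 without replicate 4 and 121 without the Tfh-like cluster. The Th1 list had 3 of 15 positive (9 when adjusted over the list alone) and none negative, and it kept its call at adjusted p = 3.5e-11 with adjusted p = 0.0225 with an estimated correlation. Other lists were called at the preset correlation alone. They were the chemokine receptor list (3 of 11 positive, 4 over the list alone, adjusted p = 0.0014, adjusted p = 0.317 with an estimated correlation) and the Tfh list (2 of 14 positive, adjusted p = 0.00016, adjusted p = 0.317 with an estimated correlation). The anergy list (1 of 14 positive, adjusted p = 0.018, adjusted p = 0.504 with an estimated correlation) and the TCR signalling list (none of 15, 2 over the list alone, adjusted p = 0.017, adjusted p = 0.504 with an estimated correlation) were called likewise. The proliferation list was called negatively (none of 22, adjusted p = 0.014, adjusted p = 0.666 with an estimated correlation). The exhaustion list had 1 of 23 positive (2 over the list alone) and a median of −0.039 against an upward test direction. Neither it (adjusted p = 0.918) nor the stemness list (1 of 18 positive and, over the list alone, 2 negative, adjusted p = 0.11) was called. Median and mean differed in sign in the uncalled myeloid (0.126 and −0.101), Th17 (−0.052 and 0.012) and Treg lists (0.059 and −0.007).

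**Figure D3:**
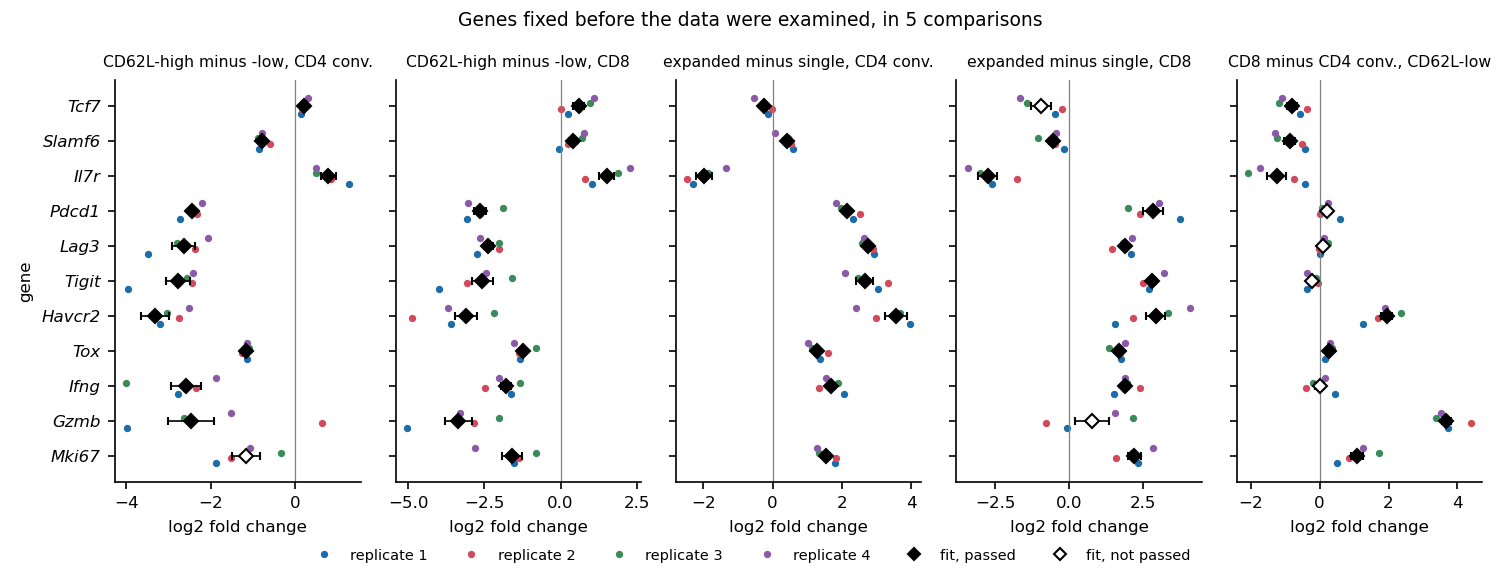
Log2 fold change (x axis, with its own range in each panel) of 11 genes fixed before the data were examined, with diamonds for the fitted value, filled where the adjusted p was under 0.05, error bars for its standard error and coloured points for the fold within each replicate, and no marks where a gene was not tested. Slamf6 lies left of zero for CD62L in CD4 conventional cells (−0.79) and right of it in CD8 cells (0.41, but −0.22 without cycling cells), while Pdcd1 lies left in both (−2.44 and −2.64).

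Within the CD62L-high CD4 conventional cells, CD11a-high cells were set against CD11a-low cells to ask whether cells that keep the homing receptor but carry an activation marker differ. In CD11a-high cells Tigit was higher by 4.81 ± 0.23 (adjusted p = 3.6e-13), Lag3 by 4.46 ± 0.20 (adjusted p = 1.7e-12), Pdcd1 by 3.48 ± 0.31, Tox by 0.98 ± 0.12 and Slamf6 by 0.60 ± 0.10. Mki67, a marker of cycling cells, was higher by 5.21 ± 0.64, Ccna2 by 5.49 ± 0.28 and the chemokine gene Ccl4 by 5.76 ± 0.21. Lef1, a partner of TCF-1, was lower by 1.82 ± 0.06, Il7r, the IL-7 receptor of naive and memory cells, by 1.66 ± 0.13, and Pdlim4 by 3.37 ± 0.19. Before the doublet filter, 104 of 352 CD62L-high CD11a-high cells with a TRB chain (29.545%, exact 95% interval 24.827 to 34.612) held 2 TRB chains, a sign of 2 cells in a droplet. The share was 4.617% of 2989 CD62L-high CD11a-low cells and 5.298% of 2869 CD62L-low CD11a-high cells. Cycling cells gave 49.3% of the UMIs of CD62L-high CD11a-high cells and 1.19% of those of CD62L-high CD11a-low cells. Of 8532 tested genes 3554 passed, 1840 higher and 1714 lower, with 1180 without cycling cells, 1751 at equal cell numbers and 2140 by the DESeq2 Wald test.

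The proliferation list was higher in 22 of 22 (adjusted p = 8.3e-65, adjusted p = 0.0327 with an estimated correlation). Exhaustion genes were higher in 15 of 16 with Tox2 at 4.6 ± 0.32 (adjusted p = 1.4e-22, adjusted p = 0.0327 with an estimated correlation). The Tfh list was higher in 11 of 11 with Icos at 2.19 ± 0.12 and Cxcr5 at 3.88 ± 0.35 (adjusted p = 8.9e-16, adjusted p = 0.031 with an estimated correlation). The Treg list was higher in 7 of 8 with Ikzf2 at 3.17 ± 0.15 (adjusted p = 9.0e-14, adjusted p = 0.031 with an estimated correlation). The stemness list was lower in 15 of 18 and higher in 2 with Satb1 at −1.58 ± 0.08 (adjusted p = 2.6e-15, adjusted p = 0.031 with an estimated correlation). These 5 lists kept their call with an estimated correlation. Cytotoxic genes were higher in 7 of 11 and lower in 1 with Nkg7 at 3.69 ± 0.12 (adjusted p = 2.2e-08, adjusted p = 0.0552 with an estimated correlation). Tissue residence genes were higher in 6 of 10 and lower in 1 (adjusted p = 5.2e-05, adjusted p = 0.0528 with an estimated correlation). Anergy genes were higher in 9 of 12 and lower in 2 (3 over the list alone) with Nrn1 at 5.23 ± 0.30 (adjusted p = 7.1e-06, adjusted p = 0.0979 with an estimated correlation). TCR signalling genes were higher in 9 of 15 and lower in 2 (10 and 2 over the list alone, adjusted p = 0.0005, adjusted p = 0.146 with an estimated correlation). Th1 genes were higher in 5 of 10 and lower in 1 with Tbx21 at 3.21 ± 0.46 (adjusted p = 0.0093, adjusted p = 0.108 with an estimated correlation). Chemokine receptor genes were higher in 3 of 5 and lower in 1 (adjusted p = 0.047, adjusted p = 0.146 with an estimated correlation). Recirculation genes were lower in 7 of 10 and higher in 1 with S1pr1 at −1.32 ± 0.10 (adjusted p = 2.0e-05, adjusted p = 0.146 with an estimated correlation). Dissociation genes were lower in 7 of 12 and higher in 1 (8 and 1 over the list alone, adjusted p = 0.00025, adjusted p = 0.146 with an estimated correlation). Interferon response genes were lower in 8 of 15 and higher in 2 (adjusted p = 0.047, adjusted p = 0.473 with an estimated correlation). Of other cells' markers, the immunoglobulin gene Igkc was higher by 1.65 ± 0.39 and Cd74, a gene of antigen-presenting cells, by 3.13 ± 0.16. Cd74 did not pass without cycling cells (2.28) or without the top 5% of doublet scores (2.57). Ighm was lower by 0.30 ± 0.11 and did not pass without replicate 2 (−0.16), 3 (−0.35) or 4 (−0.34).

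**Figure D4:**
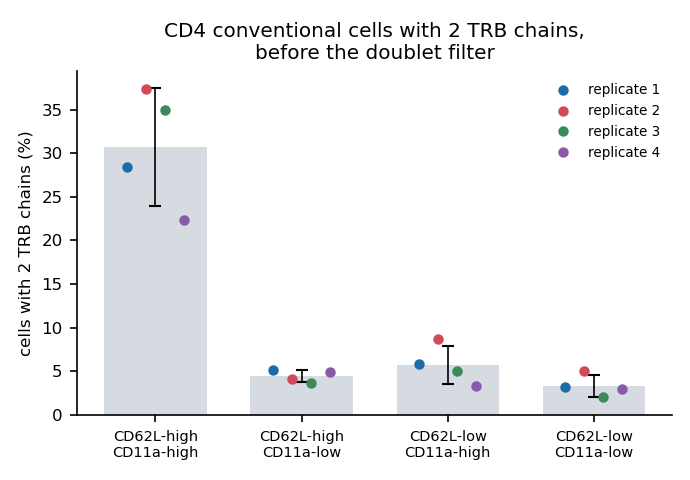
Percentage of CD4 conventional cells with a TRB chain that held 2 TRB chains before the doublet filter, by CD62L and CD11a gate, with bars for the mean of 4 libraries, error bars for the SD and points for single libraries. The CD62L-high CD11a-high bar (30.74%) stands above the other 3, of which the highest is 5.73%.

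Cells of expanded clones were compared with cells of clones seen once to ask what clonal expansion goes with in each lineage. In CD4 conventional cells, expanded clones had more Lag3 (2.76 ± 0.07, adjusted p = 1.6e-13), Il21, the cytokine of follicular and peripheral helper cells (2.99 ± 0.08, adjusted p = 2.3e-13) and Pdcd1 (2.15 ± 0.10). Tigit (2.67 ± 0.25), Havcr2 (3.56 ± 0.33) and Tox (1.27 ± 0.09) were also higher. They had less Dapl1 (−3.77 ± 0.29), Satb1 (−3.26 ± 0.14), Lef1 (−2.70 ± 0.07) and Il7r (−1.97 ± 0.23). Slamf6 was higher by 0.41 ± 0.08, but it was 0.005 without the Tfh-like cluster and 0.14 among CD62L-low cells alone, and passed in neither. Tcf7 was lower by 0.24 ± 0.07 and did not pass without replicate 3 (−0.23) or 4 (−0.13). Of 10178 tested genes 5288 passed, 2651 higher and 2637 lower, and 3410 passed by the DESeq2 Wald test. The exhaustion list had 19 of 22 higher and 1 lower, with Ctla4 at 1.73 ± 0.06 (adjusted p = 1.2e-26, adjusted p = 0.0305 with an estimated correlation). The proliferation list had 22 of 22 higher with Mki67 at 1.55 ± 0.10 (adjusted p = 1.5e-45, adjusted p = 0.0406 with an estimated correlation). Cycling cells gave 43.7% of the UMIs of expanded and 14.2% of those of single CD4 conventional clones. The stemness list had 15 of 18 lower and 2 higher with Bach2 at −1.96 ± 0.09 (adjusted p = 1.2e-23, adjusted p = 0.0301 with an estimated correlation). The Tfh list had 13 of 14 higher, with Bcl6, its master regulator, at 1.43 ± 0.11 (adjusted p = 2.3e-17, adjusted p = 0.141 with an estimated correlation). The Treg list had 11 of 15 higher and 2 lower (12 and 2 over the list alone), with Itgb8 at 2.42 ± 0.16 (adjusted p = 1.0e-09, adjusted p = 0.15 with an estimated correlation). The Th1 list had 9 of 15 higher and 1 lower, with Ifng at 1.69 ± 0.10 (adjusted p = 0.0012, adjusted p = 0.355 with an estimated correlation). TCR signalling genes were higher in 7 of 15 and lower in 1, with Irf4 at 1.83 ± 0.07 (adjusted p = 0.00011, adjusted p = 0.16 with an estimated correlation).

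Anergy genes were higher in 9 of 14 of these clones' tested members, with Dusp4 at 2.74 ± 0.09, and lower in 4, with Dgka at −1.0 ± 0.04 (adjusted p = 7.4e-05, adjusted p = 0.15 with an estimated correlation). Tissue residence genes were higher in 5 of 11 and lower in 1, with Ahr at 2.32 ± 0.14 (adjusted p = 0.0013, adjusted p = 0.141 with an estimated correlation). Chemokine receptor genes were higher in 4 of 10 and lower in 1 (5 and 1 over the list alone), with Ccr8 at 2.86 ± 0.14 (adjusted p = 0.044, adjusted p = 0.26 with an estimated correlation). Recirculation genes were lower in 7 of 10 and higher in 1, with S1pr1 at −1.61 ± 0.10 (adjusted p = 8.6e-08, adjusted p = 0.141 with an estimated correlation). Interferon response genes were lower in 11 of 17 and higher in 1, with Ly6a at −1.36 ± 0.07 (adjusted p = 7.4e-05, adjusted p = 0.405 with an estimated correlation). The cytotoxic list had 5 of 14 higher and 3 lower (6 and 3 over the list alone) and was not called (adjusted p = 0.0761), with Prf1 at −2.15 ± 0.22 and Ccl3 at 3.75 ± 0.44. The Th17 (2 of 4 higher, 3 over the list alone), dissociation (6 of 14 lower and 1 higher, 7 and 3 over the list alone) and acinar lists (3 of 6 higher) were not called. The same holds for the myeloid (2 of 3 higher, 3 over the list alone), NK (1 of 3 higher) and B cell lists (1 of 3 higher and 1 lower, median −0.154 and mean 0.267).

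In CD8 cells, expanded clones had more Tigit (2.81 ± 0.12, adjusted p = 3.2e-10), Pdcd1 (2.83 ± 0.34), Lag3 (1.88 ± 0.11), Havcr2 (2.92 ± 0.32), Tox (1.67 ± 0.09) and Tox2 (3.93 ± 0.17) than clones seen once. Ccl3 (3.86 ± 0.33) and Ccl4 (3.47 ± 0.14), chemokines of activated cytotoxic cells, Prdm1, which encodes the effector factor BLIMP-1 (2.87 ± 0.27), and Cx3cr1, a receptor of effector CD8 cells (2.98 ± 0.27), were also higher. Ccr9, the gut homing receptor (−5.31 ± 0.22, adjusted p = 3.2e-10), Igfbp4 (−6.04 ± 0.63), the interferon-induced GTPase Tgtp1 (−5.03 ± 0.21), Lef1 (−2.91 ± 0.09), S1pr1 (−2.32 ± 0.10) and Il7r (−2.74 ± 0.32) were lower. Ccr9 was also a leading gene of the naive-like clusters of CD8 cells. Slamf6 was lower by 0.54 ± 0.13 but was 0.35 and passed the other way without cycling cells, which gave 74.0% of the UMIs of expanded and 19.0% of those of single CD8 clones. Tcf7 at −0.96 ± 0.33 and Gzmb at 0.78 ± 0.58 did not pass. Of 9304 tested genes 4723 passed, 2419 higher and 2304 lower, with 2191 without cycling cells and 3115 by the DESeq2 Wald test. The exhaustion list had 19 of 21 higher and none lower, with Eomes at 1.61 ± 0.15 (adjusted p = 6.1e-23, adjusted p = 0.13 with an estimated correlation). The stemness list had 15 of 18 lower (16 over the list alone) and none higher with Txk at −1.89 ± 0.11 (adjusted p = 2.3e-22, adjusted p = 0.13 with an estimated correlation). The proliferation list had 22 of 22 higher with Mki67 at 2.21 ± 0.21 (adjusted p = 2.4e-34, adjusted p = 0.148 with an estimated correlation). The cytotoxic list had 10 of 19 higher and 1 lower, with Nkg7 at 1.03 ± 0.06 (adjusted p = 2.9e-08, adjusted p = 0.183 with an estimated correlation). Interferon response genes were lower in 13 of 16 and none higher (1 over the list alone), with Rtp4 at −2.44 ± 0.15 (adjusted p = 1.9e-10, adjusted p = 0.208 with an estimated correlation). Tfh genes were higher in 7 of 10, with Cd200 at 1.59 ± 0.18 (adjusted p = 0.00066, adjusted p = 0.148 with an estimated correlation).

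Treg-associated genes were higher in 6 of 10 and lower in 1 (8 and 1 over the list alone) in the expanded CD8 clones, with Tnfrsf9 at 2.13 ± 0.12 (adjusted p = 0.00016, adjusted p = 0.183 with an estimated correlation). Recirculation genes were lower in 7 of 11 and higher in 2, with Klf2 at −1.38 ± 0.10 (adjusted p = 1.4e-06, adjusted p = 0.179 with an estimated correlation). Tissue residence genes were higher in 6 of 12 with Xcl1 at 2.29 ± 0.15 (adjusted p = 0.0035, adjusted p = 0.413 with an estimated correlation). Chemokine receptor genes were higher in 8 of 9 and lower in 1 (adjusted p = 0.028, adjusted p = 0.413 with an estimated correlation). The Th1 list, with 8 of 14 higher and 2 lower (9 and 2 over the list alone) and Ifng at 1.90 ± 0.13, was not called (adjusted p = 0.0616). The anergy (4 of 13 higher and 4 lower, 4 and 5 over the list alone), TCR signalling (5 of 15 higher and 3 lower), dissociation (6 of 13 higher and 1 lower), myeloid (2 of 3 higher) and B cell lists (1 of 3 higher and 2 lower) were not called either. In the last of these Igkc was 3.24 ± 0.31 and Cd79b −1.90 ± 0.23.

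The clone size effect was tested for a difference between lineages, with positive values meaning a higher expanded to single ratio in CD8 than in CD4 conventional cells. Prf1 (2.05 ± 0.32), Fasl, the death ligand of cytotoxic cells (2.28 ± 0.40), and Entpd1, which encodes CD39 (2.23 ± 0.34), were relatively higher with expansion in CD8 cells. So were Cers6 (2.30 ± 0.19, adjusted p = 8.5e-08), Cd7 (1.99 ± 0.30) and Batf, an activation factor (0.65 ± 0.10). Ccr9 (−4.48 ± 0.48, adjusted p = 3.1e-06), Il6ra, the IL-6 receptor chain (−3.09 ± 0.27), Maf, a factor of helper cells (−2.44 ± 0.34), Art2b (−2.41 ± 0.33) and Stat4 (−0.92 ± 0.13) were relatively lower. Lag3 was −0.88 ± 0.18 (adjusted p = 0.00565, range over the alternatives 9.1e-11 to 0.66) and did not pass without replicate 3 (−0.93) or without cycling cells (−0.27). Slamf6 was −0.95 ± 0.26 and did not pass without replicate 2 (−0.94), 3 (−0.75) or 4 (−1.11) or without cycling cells (−0.49). Pdcd1 (0.69 ± 0.41), Tigit (0.14 ± 0.41), Tox (0.40 ± 0.14), Havcr2 (−0.58 ± 0.57) and Tcf7 (−0.69 ± 0.30) gave no call. Of 10545 tested genes 1200 passed, 591 positive and 609 negative, with 455 without replicate 3, 611 without replicate 4, 384 without cycling cells, 487 at equal cell numbers and 505 in CD62L-low cells only. No list kept its call with an estimated correlation. The proliferation list had 1 of 22 positive (5 over the list alone, adjusted p = 9.9e-06, adjusted p = 0.554 with an estimated correlation). The cytotoxic list had 2 of 19 positive and 1 negative (3 and 1 over the list alone, adjusted p = 0.036, adjusted p = 0.554 with an estimated correlation) and the γδ list 2 of 3 positive (adjusted p = 0.011, adjusted p = 0.227 with an estimated correlation). On the negative side, the interferon list had 4 of 18 (6 over the list alone, adjusted p = 0.00016, adjusted p = 0.554 with an estimated correlation). The Tfh list had 2 of 14 negative and 1 positive (5 and 1 over the list alone, adjusted p = 0.011, adjusted p = 0.554 with an estimated correlation). The stemness list had 3 of 18 negative and 2 positive (5 and 3 over the list alone, adjusted p = 0.028, adjusted p = 0.554 with an estimated correlation). The anergy list (none of 14, adjusted p = 0.028, adjusted p = 0.554 with an estimated correlation) and the B cell list (2 of 5, with 1 positive over the list alone, adjusted p = 0.036, adjusted p = 0.496 with an estimated correlation) were called on that side too. The exhaustion list, 4 of 23 positive and 3 negative (6 and 3 over the list alone), was not called (adjusted p = 0.22). Neither were the recirculation list (median 0.23 and mean −0.249) and the Th1 list (median 0.121 and mean −0.104).

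CD8 cells were set against CD4 conventional cells to ask which programmes the lineages differ in, the contrast behind the study's question of resistance to exhaustion in CD4 responses. Lineage genes separated the gates, with Cd8a at 6.42 ± 0.18, Cd8b1 at 5.93 ± 0.12, Cd4 at −6.39 ± 0.32 and Zbtb7b, the CD4 lineage factor ThPOK, at −4.79 ± 0.12. CD8 cells had more Klrd1, an NK receptor chain (3.98 ± 0.08, adjusted p = 5.5e-09), and Klrk1, which encodes NKG2D (4.50 ± 0.14). They also had more of the granzyme genes Gzma (3.97 ± 0.22) and Gzmb (3.74 ± 0.10), of Itgae, which encodes the residence integrin CD103 (4.37 ± 0.33), and of Cd160 (3.29 ± 0.10). CD4 conventional cells had more Cd40lg, the helper ligand for B cells (−5.67 ± 0.15), Maf (−4.18 ± 0.09, adjusted p = 1.1e-08), Il21 (−4.12 ± 0.14) and Tnfsf8 (−2.54 ± 0.20). Havcr2 was higher in CD8 cells by 2.08 ± 0.18, while Pdcd1 at 0.33 ± 0.08, Tox at 0.33 ± 0.06 and Lag3 at 0.22 ± 0.07 passed by small margins and Tigit at −0.10 ± 0.08 did not. Lag3 did not pass without replicate 3 (0.15) or 4 (0.22), and with 1 cell per clonotype Pdcd1 was −0.13 and Tox −0.09, neither passing. Tcf7 (−0.71 ± 0.10), Il7r (−1.04 ± 0.14) and S1pr1 (−0.88 ± 0.11) were lower in CD8 cells, as was Slamf6 (−0.57 ± 0.13), which did not pass without replicate 3 (−0.47). Cycling cells were 17.17% ± 6.82 of CD8 and 6.63% ± 0.98 of CD4 conventional cells, and gave 46.3% ± 12.6 of the CD8 and 23.1% ± 1.8 of the CD4 conventional UMIs. Of 11104 tested genes 4780 passed, 2454 higher and 2326 lower in CD8 cells, with 2962 without replicate 4, 3047 without cycling cells, 2605 with 1 cell per clonotype and 3083 by the DESeq2 Wald test.

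Among the lists, only the cytotoxic one kept its call with an estimated correlation, with 19 of 19 members higher in CD8 cells (adjusted p = 1.2e-61, adjusted p = 0.021 with an estimated correlation). The proliferation list was higher in 22 of 22 with Pclaf at 1.42 ± 0.12 (adjusted p = 2.0e-13, adjusted p = 0.365 with an estimated correlation). The tissue residence list was higher in 6 of 13 and lower in 3 with Xcl1 at 3.05 ± 0.10 (adjusted p = 0.00075, adjusted p = 0.339 with an estimated correlation). The γδ list was higher in 2 of 3 with Tcrg-C4 at 3.67 ± 0.15 (adjusted p = 2.0e-08, adjusted p = 0.0662 with an estimated correlation). The Tfh list was lower in 11 of 14 and higher in 1, with Cxcr5 at −1.37 ± 0.10 (adjusted p = 4.6e-22, adjusted p = 0.0662 with an estimated correlation). The anergy list was lower in 8 of 14 and higher in 1, with Izumo1r, the folate receptor FR4, at −2.13 ± 0.22 (adjusted p = 6.5e-05, adjusted p = 0.339 with an estimated correlation). The TCR signalling list was lower in 9 of 15 and higher in 2 (10 and 2 over the list alone), with Cd5 at −0.90 ± 0.07 (adjusted p = 0.0053, adjusted p = 0.393 with an estimated correlation). The Treg list was lower in 10 of 16 and higher in 2, with Tnfrsf4, which encodes OX40, at −2.18 ± 0.14 (adjusted p = 0.00038, adjusted p = 0.339 with an estimated correlation). Foxp3 counts as 1 of the 2 higher genes (7.34 ± 0.75), a value set by the gate, since cells with its mRNA were taken out of the CD4 conventional cells. The stemness list was lower in 11 of 18 and higher in 3, with Myb at 1.04 ± 0.09 (adjusted p = 0.045, adjusted p = 0.664 with an estimated correlation). It was not called without the replicate block (adjusted p = 0.16). Dissociation genes were lower in 10 of 14 and higher in 2, with Hspa1a at −1.27 ± 0.06 (adjusted p = 5.1e-05, adjusted p = 0.339 with an estimated correlation). The exhaustion list, with 14 of 23 higher and 7 lower, was not called (adjusted p = 0.0517). Nor were the Th1 (6 of 15 higher and 4 lower, 6 and 5 over the list alone), recirculation (4 of 11 higher and 4 lower), interferon (1 of 18 higher and 3 lower, 1 and 1 over the list alone) and Th17 lists (2 of 4 lower). The chemokine receptor list (5 of 11 higher and 5 lower, median −0.164 and mean 0.07) was not called either. Of other cells' markers, the endocrine (3 of 4 lower), B cell (2 of 6 higher and 1 lower, with Cd79b at 2.45 ± 0.32), myeloid (2 of 9 higher), NK (2 of 4 higher and 1 lower) and acinar lists (none of 8) were not called. The iNKT and endothelial lists had too few tested members for a list test, and of their genes Slamf1 was −1.23 ± 0.14 and Pecam1 −1.22 ± 0.17.

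The lineage comparison was also restricted to CD62L-low cells, which lowers the share of naive-like cells without removing them. Of the CD8 cells in their larger naive-like cluster 58.06% ± 15.39 were CD62L-high. Of the CD4 conventional cells in theirs 69.52% ± 6.51 and 74.98% ± 5.14 were. The rest stayed in, so the restriction cannot settle whether the lineage difference rests on naive-like cells. Cytotoxic genes stayed higher in CD62L-low CD8 cells, with Klrd1 at 4.18 ± 0.11 (adjusted p = 1.3e-08), Gzmb at 3.68 ± 0.13 and Prf1 at 2.64 ± 0.10. Maf at −4.42 ± 0.11, Il21 at −4.30 ± 0.14 and Cd40lg at −5.71 ± 0.15 stayed lower. Pdcd1 (0.23 ± 0.10), Lag3 (0.09 ± 0.07) and Tigit (−0.22 ± 0.08) did not pass. Havcr2 (1.94 ± 0.17) was higher and Tcf7 (−0.80 ± 0.14) and Slamf6 (−0.87 ± 0.16) were lower in CD8 cells. Tox at 0.27 ± 0.07 passed, but not without replicate 3 (0.23) or 4 (0.25). Of 10842 tested genes 4227 passed, 2199 higher and 2028 lower, with 2761 without replicate 3, 2416 without replicate 4, 2333 without cycling cells and 2673 by the DESeq2 Wald test. The cytotoxic list was higher in 19 of 19 (adjusted p = 3.0e-59, adjusted p = 0.0084 with an estimated correlation). The proliferation list was higher in 22 of 22 (adjusted p = 5.6e-12, adjusted p = 0.433 with an estimated correlation), as was the γδ list in 2 of 3 (adjusted p = 7.6e-09, adjusted p = 0.0615 with an estimated correlation). The tissue residence list was higher in 6 of 13 and lower in 3 with Crtam at 2.63 ± 0.11 (adjusted p = 0.00063, adjusted p = 0.309 with an estimated correlation). The Tfh list was lower in 11 of 14 with 1 higher (adjusted p = 2.0e-27, adjusted p = 0.0562 with an estimated correlation). The Treg list was lower in 10 of 16 with 1 higher (11 and 1 over the list alone, adjusted p = 3.6e-06, adjusted p = 0.232 with an estimated correlation). The anergy list was lower in 8 of 14 with 1 higher and Tbc1d4 at −2.38 ± 0.10 (adjusted p = 2.1e-05, adjusted p = 0.379 with an estimated correlation). The dissociation list was lower in 10 of 14 and higher in 2 (adjusted p = 1.9e-05, adjusted p = 0.309 with an estimated correlation). The TCR signalling list was lower in 10 of 15 and higher in 2 (11 and 2 over the list alone), with Irf4 at −0.74 ± 0.07 (adjusted p = 0.0018, adjusted p = 0.433 with an estimated correlation). The exhaustion list, 12 of 23 higher and 6 lower (13 and 7 over the list alone, adjusted p = 0.201), and the stemness list, 3 of 18 higher and 9 lower (4 and 9 over the list alone, adjusted p = 0.267), were not called. Of other cells' markers, 4 of 5 B cell genes were higher and 1 lower, and that list was not called (adjusted p = 0.266). The chemokine receptor list (median −0.235 against an upward test direction) and the recirculation list (median 0.222 against a downward one) were not called.

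V gene usage was compared between CD8 and CD4 conventional clonotypes (n = 4 libraries a side), counting each clonotype once, to ask whether the lineages draw on different receptors. Of 19 tested TRBV genes 9 were used more and 6 less by CD8 cells, and of 31 TRAV genes 5 more and 10 less, each in 4 of 4 libraries. TRBV12-1 made up 3.41% of CD8 and 0.465% of CD4 conventional TRB chains (2.73 ± 0.31), TRBV12-2 2.07% and 0.247% (2.97 ± 0.29, adjusted p = 3.6e-11), TRBV14 6.12% and 2.44% (1.41 ± 0.19) and TRBV3 6.54% and 2.57% (1.41 ± 0.20). The TRBV12-2 entry rests on 34 CD8 and 14 CD4 conventional clonotypes. A joint entry of TRBV12-2 and TRBV13-2 held 10.11% of CD8 and 13.24% of CD4 conventional chains. It leaned the other way (−0.34 ± 0.24) without a call, so the lineage difference of TRBV12-2 as a whole was not resolved. TRBV15 was lower in CD8 cells, 1.92% against 6.68% (−1.64 ± 0.27), as were TRBV20 (−1.46) and TRBV31 (−1.26). Among α chains TRAV16N made up 11.49% ± 2.6 of CD8 and 3.52% ± 0.56 of CD4 conventional chains (1.67 ± 0.12, adjusted p = 5.5e-23), and TRAV12D-2 was also higher (1.30 ± 0.19), while TRAV4-2 (−2.12 ± 0.30) and TRAV14-3 (−2.28 ± 0.52) were lower. Many mouse TRAV genes have near-identical copies, so the named copy is uncertain. Without replicate 1, 19 V genes passed in place of 30.

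**Figure D5:**
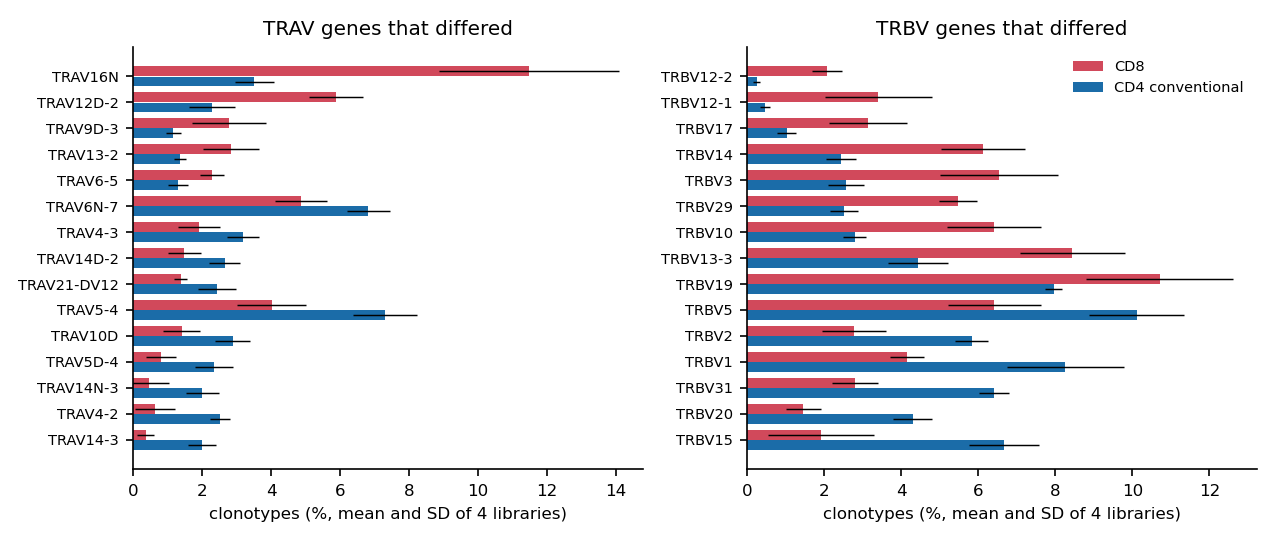
Percentage of clonotypes using each TRAV (left) and TRBV (right) gene that differed between the lineages, in CD8 (red) and CD4 conventional cells (blue), with bars for the mean and error bars for the SD of 4 libraries. The widest gap in percent is that of TRAV16N (11.49% against 3.52%).

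Clones of at least 2 cells were also checked for spanning the CD62L-high and CD62L-low states, against 1000 shuffles of the state within each library. In CD4 conventional cells 62 of 408 clones spanned them, 15.12% ± 3.97 per library against 23.07% ± 8.85 when shuffled, a difference of −7.95 ± 9.79 points (exact permutation test over 4 libraries, two-sided p = 0.375, smallest possible 0.13). In CD8 cells 26 of 132 did, 19.73% ± 6.59 against 24.93% ± 3.7, a difference of −5.20 ± 7.11 points (exact two-sided p = 0.25). The libraries differed in this. In CD4 conventional cells of replicates 1 and 2 the difference was −19.37 and −12.49, with 0 of 1000 shuffles as low, and in replicates 3 and 4 it was −2.13 and 2.18. In CD8 cells it was −15.32 in replicate 1, with 1 of 1000 shuffles as low, and −4.65, −1.70 and 0.87 in replicates 2 to 4. Without replicate 1 the mean differences were −4.11 and −1.81. For clones of at least 3 cells they turned to 1.51 ± 1.0 and 0.22 ± 2.15, and with another antibody gate the CD8 difference was 0.24 ± 1.55.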

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

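The cycling cell test of Slamf6 and the TRB chain test of the CD11a-high cells were chosen only after the results were seen, as were the settings that leave out the Tfh-like cluster, keep cells with a CD11a count of at least 20, or leave out cycling cells in the interactions and the CD11a comparison.

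Slamf6 was the gene of the stemness list whose CD62L effect differed between the lineages, with −0.79 ± 0.05 in CD4 conventional cells and 0.41 ± 0.13 in CD8 cells, where it turned to −0.22 without cycling cells, an interaction of 1.192 (adjusted p = 0.0148, range over the alternatives 2.9e-06 to 0.129). Low-antibody barcodes in the CD8 gate were argued against by an interaction of 1.21 among cells with a CD11a count of at least 20, and cycling cells as the whole cause by 0.789 without them, both still called. Large clones were argued against for the CD4 side alone, where 1 cell per clonotype left −0.744, while the CD8 value fell to 0.06 and the interaction was not run. Whether Tfh-like cells on the CD62L-low side account for it cannot be told apart from these tests, since without their cluster the CD4 fall was −0.425 (adjusted p = 2.3e-06) but the interaction dropped to 0.82 and lost its call. A lineage difference in how Slamf6 follows CD62L stays a possible explanation that was not tested in other samples.

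The activation genes of CD62L-high CD11a-high CD4 conventional cells came with a high rate of barcodes with 2 TRB chains, 29.545% before the doublet filter against at most 5.298% in the gates that share a marker with them. This is consistent with doublets of a CD62L-high and a CD11a-high cell, of which the filter removes only those whose TRB chains were both read. Cycling cells were argued against as the whole cause, since 3 of 3 of Lag3, Pdcd1 and Tigit still passed without them. A population that carries both proteins was not tested apart from doublets and may be present as well.

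The clone size effect differed between lineages for 1200 genes (455 without replicate 3, 611 without replicate 4) and the CD62L effect for 256 genes (94 without replicate 3, 60 without replicate 4). Among the inhibitory receptor and stemness genes named in every comparison, Lag3 (−0.882, adjusted p = 0.00565, range over the alternatives 9.1e-11 to 0.66) and Slamf6 (−0.951, adjusted p = 0.0417) differed in their clone size effect, both relatively lower with expansion in CD8 cells. Lag3 was −0.27 and lost its call without cycling cells, and it did not pass without replicate 3 (−0.93). Slamf6 did not pass without replicate 2 (−0.94), 3 (−0.75) or 4 (−1.11) or without cycling cells (−0.489), where its effect in CD8 cells turned from −0.54 to 0.347 and passed. In CD4 conventional cells its effect was 0.005 without the Tfh-like cluster.

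Tigit in CD62L-high against CD62L-low CD4 conventional cells was −3.96 in replicate 1, apart from the nearest other replicate at −2.56. It was the only such value in 126 groups of 4 libraries, where chance alone gives about 6.3.

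Cluster 23, of 279 cells and without a name, paired TRAV11 with TRAJ18, the invariant α chain of NKT cells, in 62 of its 171 cells with a TRA chain (36.257%, exact 95% interval 29.056 to 43.944), 12 to 19 cells in each library. In other clusters of over 100 cells the share was at most 0.546%. No comparison was aimed at these cells, but the cluster was not left out. It gave 70 of the CD4 conventional cells, 30 of the CD8 cells and 4 of the Treg compared.

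A CD11a count under 20 was found for 5.3%, 6.6%, 37.3% and 31.2% of the barcodes of replicates 1 to 4. CD11a counts entered the comparisons through the gates, the naming of T cell state clusters and the setting with a count of at least 20.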

How the results depend on the processing

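Counts and shares were recomputed under the alternatives, and 267 of these values stayed, 53 moved and 4 changed sign. A count stayed when within 1.5 times the reported one, and a population share when within 1 SD of it. For the differences in expanded share and in spanning only the sign was judged, whatever the size. Of the values of named genes 14182 kept their call or stayed without one, 685 lost the call, 262 gained it and 15 changed sign. A sign change was counted only with a call in at least 1 of the settings compared. The settings with cells chosen after seeing the data are a CD11a count of at least 20, CD62L-low cells only, the Tfh-like cluster left out, replicates 1 and 2 only, the top doublet scores left out and, for the CD62L-low lineage comparison, the CD11a comparison and the interactions, cycling cells left out. Where a setting uses fewer cells or libraries, this lowers the counts by its construction, and elsewhere the cause was not tested.

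With the DESeq2 Wald test 3083 genes passed for CD8 against CD4 conventional cells, 2673 for the same in CD62L-low cells, 2946 for CD62L in CD4 conventional cells, 1978 for CD62L in CD8 cells, 2140 for CD11a, 3410 for clone size in CD4 conventional cells and 3115 for clone size in CD8 cells. Without cycling cells the counts were 3047, 2333, 1660 (CD62L, CD8), 1180 (CD11a), 2191 (clone size, CD8) and 384 (clone size interaction). With 1 cell per clonotype they were 2605 for the lineages, 3017 for CD62L in CD4 conventional cells and 558 in CD8 cells. Equal cell numbers gave 1751 for CD11a and 487 for the clone size interaction, and CD62L-low cells only gave 505 for the latter. Leaving out the Tfh-like cluster gave 121 for the CD62L interaction. Without the replicate block 106 genes passed for the CD62L interaction and 709 for the clone size interaction, 5 lists were called for the latter, and the block changed no other count by over 1.5 times. Replicates 1 and 2 only gave 3046 and 2647 for the lineage comparisons, 1560 for CD62L in CD8 cells, 92 for the CD62L interaction, 2285 for CD11a, 3120 for clone size in CD8 cells and 270 for its interaction.

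With each replicate left out in turn the range was 2962 to 4677 for CD8 against CD4 conventional cells, 2416 to 4174 in CD62L-low cells, 1868 to 3040 for CD62L in CD8 cells, 60 to 187 for the CD62L interaction, 455 to 1088 for the clone size interaction and 19 to 29 for V genes. With an estimated correlation the lists called numbered 1 for the lineages, 1 in CD62L-low cells, 0 for CD62L in CD4 conventional and 0 in CD8 cells, 1 for the CD62L interaction, 5 for CD11a, 3 and 0 for clone size in CD4 conventional and CD8 cells and 0 for its interaction.

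Without thinning, where the larger population has more chances to repeat a clone, the difference in expanded share was −3.9 from Treg to CD4 conventional cells, 12.45 from CD8 to CD4 conventional cells, 14.83 for the same in CD62L-low cells and −25.76 for CD62L in Treg. For clones of at least 3 cells it was 3.46 from Treg to CD4 conventional cells and −9.33 for CD62L in Treg. The spanning difference was 1.51 (CD4 conventional) and 0.22 (CD8) for clones of at least 3 cells, and 0.24 (CD8) with another antibody gate. With lineage by UMIs CD8 cells were 24.99%, cells of both lineages 0%, and CD11a-high cells 52.32% (4.09% to 98.25% over the libraries) of CD62L-high and 64.32% of CD62L-low CD4 conventional cells. With a CD11a count of at least 20, CD4 conventional cells were 53.63%.

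The sign changes so counted were, without cycling cells, Itgal (0.129) between the lineages, Eomes (−0.372) and Slamf6 (−0.22) for CD62L in CD4 conventional and CD8 cells, Cxcr4 (−0.293), Cd8b1 (0.051) and Slamf6 (0.347) for clone size in CD8 cells and Cxcr4 (−0.835) for its interaction. With 1 cell per clonotype they were Igkc (−0.158), Pdcd1 (−0.13) and Tox (−0.088) between the lineages. Leaving out the Tfh-like cluster turned Igkc (1.395) for clone size in CD4 conventional cells, where Tmem176b was −0.002 without the top doublet scores and −0.301 in CD62L-low cells only. Tyrobp (−0.989) for CD62L in CD4 conventional cells turned with replicates 1 and 2 only, and TRAV6N-7 (0.053) with cells in place of clonotypes.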

Other observations

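All results of the next 2 paragraphs, and the comparison of expanded shares between CD62L-low CD8 and CD4 conventional cells, were chosen after the data were seen.

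The Treg-like clusters differed in CD62L and in expanded clones. The larger one held 49.55% ± 4.89 (SD, n = 4) of the Treg, with 8.33% ± 1.19 CD62L-high and 39.38% ± 12.24 in expanded clones. The smaller one held 31.07% ± 5.99, with 54.85% ± 4.6 CD62L-high and 3.54% ± 2.82 in expanded clones. A cycling-like cluster held 8.59% ± 2.1 of the Treg, with 49.56% ± 20.25 in expanded clones. Clones of at least 2 cells that held Treg or CD4 conventional cells contained both in 63 of 507 cases, 12.54% ± 3.49 per library against 37.15% when the labels were shuffled. The difference of −24.61 ± 9.0 points had an exact two-sided permutation p of 0.13, the smallest 4 libraries allow.

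Receptors were rarely shared between libraries. The same paired V genes and CDR3 amino acids were seen in at least 2 libraries for 11 of 5300 CD4 conventional and 2 of 1548 CD8 receptors, and for 0 of 976 Treg receptors. Single chains were shared more often, with TRB CDR3 sequences in at least 2 libraries for 98 of 5089 CD4 conventional, 17 of 1507 CD8 and 5 of 954 Treg chains, and TRA CDR3 sequences for 400 of 4503, 62 of 1454 and 23 of 930. Among CD62L-low cells alone, 55.34% ± 16.14 of CD8 and 31.71% ± 1.75 of CD4 conventional cells were in expanded clones at equal cell numbers, a difference of 23.63 ± 17.05 points that was positive in 4 of 4 libraries (exact two-sided permutation p = 0.13, the smallest possible). Without thinning it was 14.83 ± 15.15 and positive in 3 of 4 libraries, with −2.51 in replicate 1.

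Other splits of the same sums were counted for each comparison. The populations of a comparison come from the same libraries, so only the 8 splits that part all 4 pairs can stand in for the real one, and 8 splits are too few for a share under 0.05. In each case 1 split, the real one, reached its count. The real value and the highest of the other splits were 4780 and 0 for CD8 against CD4 conventional cells, 4227 and 0 for the same in CD62L-low cells, 4932 and 0 for CD62L in CD4 conventional cells and 3057 and 0 in CD8 cells. They were 3554 and 0 for CD11a, 5288 and 0 for clone size in CD4 conventional cells, 4723 and 0 in CD8 cells and 30 and 0 for V genes. For the interactions they were 256 and 0 for CD62L and 1200 and 0 for clone size. The 24 further splits of the comparisons of 2 populations differ in keeping both populations of some libraries on the same side, and their highest counts were 815 for the lineages in CD62L-low cells, 3 for V genes and 0 elsewhere.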
